A study of Oryza sativa with 36 samples.

How the data were processed

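RNA-seq had been run on leaves of rice (Oryza sativa, japonica, TNG67) at the tillering stage, from plants grown directly from seed or regenerated from calli after combinations of transformation treatments. The labels give 9 groups of 2 biological replicates each, 18 RNA-seq libraries in all. The group names Seedling, Callus, Callus+AM, Ag, AgTi, AgBi, AMT+Ab, AMT+Hb and PB are used as the labels give them, because AM, Ag, Ti, Bi, AMT, Ab, Hb and PB are not spelled out in the sources used here. That the 8 groups other than Seedling were regenerated from calli is a reading of the growth protocol. The 18 bisulfite samples of the same groups are not analysed here.

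The authors deposited a table of estimated counts per gene and a table of FPKM values for the same 18 libraries. TopHat, Cuffnorm and Cuffdiff are named per the submitters' processing notes, without versions or order. The aligner settings, the genome build and whether the counting used strand are not given in the sources used here. Of the deposited count values, 0.707% were not whole numbers, so the counts were treated as estimates and rounded to whole numbers before testing. Among 10147 genes with at least 200 counts in every library, the deposited counts divided by the deposited FPKM lay within 1% of a common factor per library for 82.9% to 89.9% of genes. Both tables list 55986 genes, of which 55801 have LOC_Os identifiers and 96 and 89 have ChrUn and ChrSy identifiers, with 0 counts in total. These and others, 13435 genes in all, were at 0 in all 18 libraries.

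Gene names could be matched for 1 identifier only, through the synonyms of the RefSeq gene table of assembly ASM3414082v1, and the files pair no other identifier with a name. The gene lists fixed before the data were examined hold names, so neither their member counts nor the planned camera tests could be run, and no theme is named. The rule for named genes, also fixed before the data were examined, then allows at most 2 identifiers that were higher and 2 that were lower per comparison. These have a mean log2 CPM (counts scaled to library size) of at least 1 over all libraries and an adjusted p below 0.05. They have the largest absolute log2 fold changes among genes whose libraries do not overlap between the groups compared. For the comparison of all 8 groups with Seedling, the 2 Seedling libraries had to lie on the same side of the mean of every group. The chromosome of a gene was read from its identifier, and no coordinates are given. Genes that share reads with near-identical copies or overlapping genes could not be told apart in these tables.

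Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 26374 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with a coefficient per group was fitted to all 18 libraries with robust estimation, which left 9 residual degrees of freedom, at a common dispersion of 0.146. The 15 comparisons were tested with glmQLFTest and adjusted by the Benjamini-Hochberg method within each comparison, with calls at adjusted p below 0.05. All adjusted p-values below come from edgeR unless another tool is named. The standard error of a log2 fold change was derived from its F statistic. PB was compared with the equal-weight mean of AMT+Ab and AMT+Hb, and the 8 groups together were compared with Seedling as the equal-weight mean of their coefficients. Levels are TMM-scaled CPM as mean ± SD over libraries.

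Total counts ranged from 26609812 to 52643975 per library, so 3 counts correspond to between 0.057 and 0.113 CPM before scaling. Folds against a group at 0 are lower bounds computed against 3 counts over the whole group. Folds against a group with few counts carry a 95% exact Poisson interval of the lower group. Bounds and intervals cover counting error only. The 2 libraries of a group differed by far more than counting noise in every group, so no library was counted as a duplicate.

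The alternatives fixed beforehand were relative log expression size factors, no filter on low counts and the Wald test of DESeq2 1.42.0. Others were limma 3.58.1 with an intensity trend on log2(FPKM + 1) for 20907 genes with a mean FPKM of at least 1, and a fit of only the groups compared. The rest were the replicate number as a block, a test against a fold of at least 1.5 (glmTreat) and leaving out each library in turn. When 1 library of a group is left out, the remaining library is assumed to vary like the other groups. Alternatives chosen after seeing the data are named as such in the closing section. The groups have 2 libraries each, so splits of the samples were not drawn.

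The tests were tried on simulated counts for 26374 genes, drawn with the library sizes and dispersions of the real data and with 200 changed genes. The compared groups were set to the mean over all groups before the changes. In the simulated AgTi against Ag comparison, edgeR recovered 0 of 50 genes changed 1.5-fold, 3 of 50 changed 2-fold, 20 of 50 changed 4-fold and 32 of 50 changed 8-fold, with 4 false calls. DESeq2 recovered 33 of 50 genes changed 4-fold and 45 of 50 changed 8-fold, with 50 false calls. In the simulated PB against Seedling comparison, edgeR recovered 22 of 50 genes changed 4-fold and 40 of 50 changed 8-fold, with 3 false calls.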

Results

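Leaf transcriptomes of rice plants grown from seed were set beside those of plants regenerated from calli that had gone through different parts of a transformation procedure. Each of the 9 groups had 2 libraries. The 4 Seedling and Callus libraries held 41582054 to 52643975 counts, and the 14 libraries of the other 7 groups held 26609812 to 33222427. Where 1 of these 7 groups is compared with Seedling or Callus, group and depth set differ together. Callus against Seedling lies within the deeper set, and comparisons among the other 7 groups lie within the shallower set. Genes are given by identifier and chromosome, because the files do not pair identifiers with names. For the same reason, differences between groups in sampling time, stress or light could not be checked by marker genes. Differences between groups given below may come from the state of the plants when sampled as well as from regeneration or treatment.

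**Figure D1:**
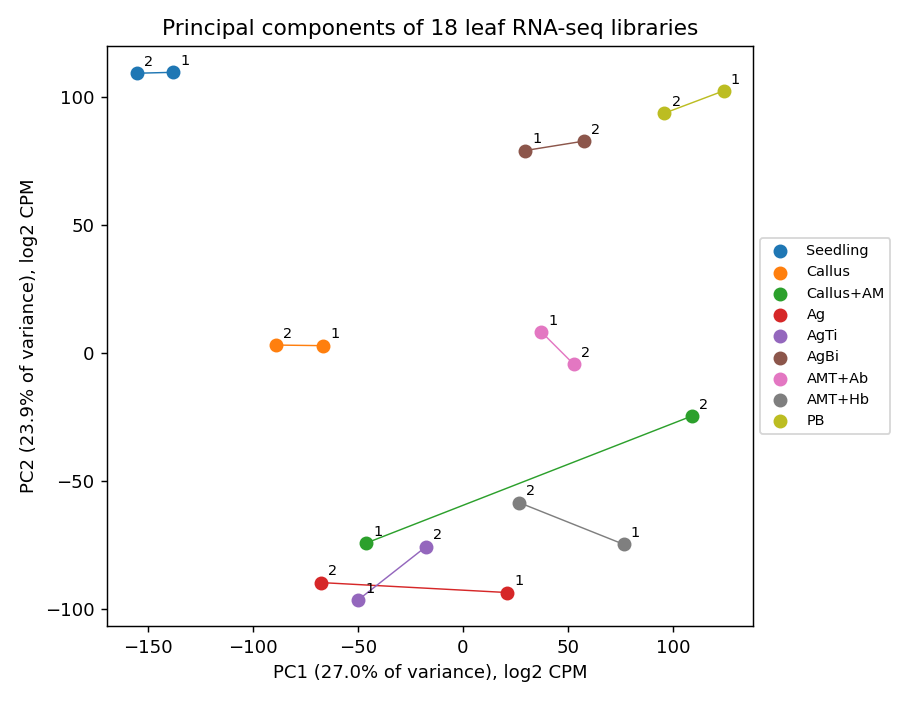
Principal components of log2 CPM for 26374 genes, with PC1 (26.99% of the variance) on the x axis and PC2 (23.9%) on the y axis. Points are libraries numbered by replicate, lines join the 2 libraries of a group, Seedling, AgBi and PB lie at the top, and the libraries of Callus+AM and Ag lie apart from their own partners.

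Of the 18 libraries, 12 had the library of their own group as the closest by Spearman correlation across genes, which are not independent replicates. The exceptions were the libraries of Callus+AM, Ag and AgTi. Callus+AM replicate 1 was closest to AgTi replicate 2 (rho = 0.986) and Ag replicate 2 to AgTi replicate 1 (rho = 0.985). Callus+AM replicate 2 was closest to AMT+Hb replicate 1 (rho = 0.950), and Ag replicate 1 to AMT+Hb replicate 2 (rho = 0.967). The 2 Callus+AM libraries were more than 10-fold apart at 1074 genes, against 420 genes in Ag, 298 in Callus, 287 in PB, 257 in AgBi, 114 in AMT+Hb, 70 in AgTi, 60 in AMT+Ab and 48 in Seedling.

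What regenerated plants had in common was addressed by comparing the 8 callus-derived groups together with Seedling. LOC_Os01g08020 on chromosome 1 was lower in all 16 regenerated libraries, at 9.22 ± 15.8 CPM (SD, n = 16) against 201 ± 3.69 CPM in Seedling (SD, n = 2). Its log2 fold change was -5.68 (SE 0.303, edgeR adjusted p = 1.34e-07). LOC_Os02g04510 on chromosome 2 was also lower, at 16.1 ± 40.2 CPM against 252 ± 122 CPM (log2 fold change -5.64, SE 0.424, edgeR adjusted p = 1.51e-06). Within the deeper set, LOC_Os01g08020 was at 3.29 and 3.01 CPM in the Callus libraries and at 203.5 and 198.3 CPM in the Seedling libraries. AgBi replicate 1 held the highest regenerated level of these genes, 64.6 CPM for LOC_Os01g08020 and 165 CPM for LOC_Os02g04510. Seedling replicate 1 held 166 CPM of LOC_Os02g04510 and replicate 2 held 338 CPM, so in AgBi replicate 1 this gene was near a Seedling level. Higher than in Seedling were LOC_Os05g04500 and LOC_Os05g09740, both on chromosome 5 and both at 0 counts in Seedling. LOC_Os05g04500 averaged 47.3 ± 42.5 CPM, at least 1140-fold higher (edgeR adjusted p = 0.0122), and LOC_Os05g09740 averaged 43.8 ± 41.3 CPM, at least 1057-fold higher (edgeR adjusted p = 0.0248). In Callus these genes were near 0, between 0.105 and 1.91 CPM for LOC_Os05g04500 and between 0 and 0.145 CPM for LOC_Os05g09740. Ag replicate 2 was also low, at 0.616 CPM for LOC_Os05g04500 and 0.241 CPM for LOC_Os05g09740. AgTi replicate 1 held 0.347 CPM of LOC_Os05g09740. The folds over all groups therefore do not hold for each regenerated library. Without Seedling replicate 1 or 2 the calls of LOC_Os05g04500 and LOC_Os05g09740 ended (edgeR adjusted p 0.0807 to 0.142), and that of LOC_Os05g09740 also ended without Callus replicate 1 (edgeR adjusted p = 1), where the remaining Callus library held 0 counts. LOC_Os05g04500 had bounds of 597-fold and 543-fold without Seedling replicate 1 and 2, and LOC_Os05g09740 of 554-fold and 504-fold. For LOC_Os02g04510 the log2 fold change was -5.03 without Seedling replicate 2.

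In all, 4501 genes were higher and 5409 lower in the 8 groups together, of which 3701 and 3524 changed over 2-fold. The total of 9910 was 5583 without Seedling replicate 1, 4715 without Seedling replicate 2 (1618 higher, 3097 lower) and 5829 against 1.5-fold. Called in the same direction in each of the 8 separate comparisons with Seedling were 646 higher and 720 lower genes, Callus against Seedling within the deeper set included. The 8 comparisons share the Seedling libraries, and 10 simulations of unchanged groups against shared controls gave 0 such genes each. These simulations held no deviation of Seedling beyond random spread, so they set no baseline for shared controls. Independent lists of the same sizes would share 0.0115 genes, but lists with the same controls are not independent. With 2 Seedling libraries the controls could not be split, so an unknown part of the shared genes may come from the shared controls. Another 546 genes were higher than Seedling in at least 1 group and lower in at least 1 other.

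**Figure D2:**
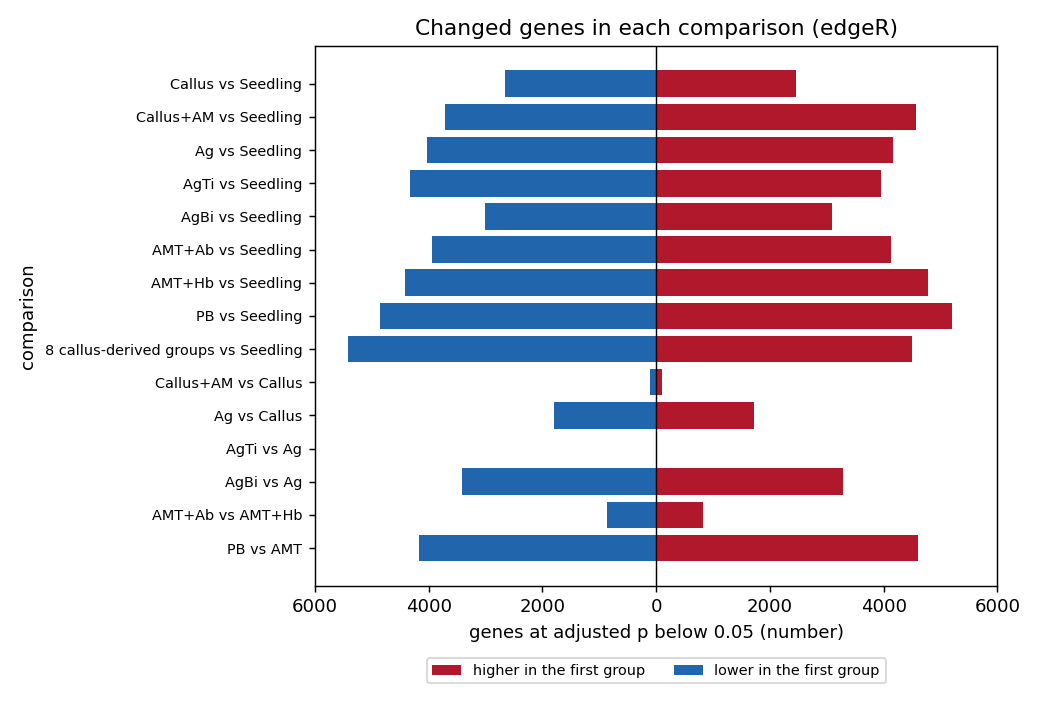
Number of genes at adjusted p below 0.05 (x axis) in each of the 15 comparisons (y axis), with higher genes to the right of 0 and lower genes to the left. PB against Seedling had the most calls, 5208 higher and 4850 lower, and AgTi against Ag had 0.

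Regeneration without a further named treatment was addressed by Callus against Seedling. LOC_Os11g13800 on chromosome 11 stood at 40.04 ± 1.82 CPM in Callus (SD, n = 2), with 1 count in both Seedling libraries together. The ratio was 2897-fold (95% interval 520 to 114400, edgeR adjusted p = 4.48e-07). LOC_Os03g16920 on chromosome 3 was lower, at 0.533 ± 0.139 against 71.9 ± 17.4 CPM (log2 fold change -7.06, SE 1.23, edgeR adjusted p = 0.00248). LOC_Os09g32000 on chromosome 9 was lower as well, at 1.40 ± 1.30 against 156 ± 78.1 CPM (log2 fold change -6.81, SE 1.22, edgeR adjusted p = 0.00285). LOC_Os03g14654 on chromosome 3 passed the test (edgeR adjusted p = 0.0224) with 127.5 CPM in Callus replicate 1 and 0.737 CPM in replicate 2. Its call ended without Callus replicate 1 or either Seedling library (edgeR adjusted p 0.127 to 0.429), and its log2 fold change of 9.78 was 3.35 without Callus replicate 1 and 10.77 without Callus replicate 2. LOC_Os11g13800 was at least 506-fold higher without Seedling replicate 1, and its ratio was 1380-fold (95% interval 248 to 54520) without Seedling replicate 2. For LOC_Os09g32000 the log2 fold change was -6.18 without Seedling replicate 2, -8.32 without Callus replicate 1 and -6.08 without Callus replicate 2. Altogether 2454 genes were higher and 2656 lower. The total of 5110 fell to 2840 without Seedling replicate 1, 2246 without Seedling replicate 2 (833 higher, 1413 lower), 2015 without Callus replicate 1 and 2764 without Callus replicate 2, and 3016 genes passed a test against 1.5-fold.

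In Callus+AM against Seedling, LOC_Os03g16020 on chromosome 3 was lower at 0.430 ± 0.0942 CPM against 235 ± 238 CPM (SD, n = 2 each; log2 fold change -9.09, SE 1.62, edgeR adjusted p = 0.00165). LOC_Os07g08150 on chromosome 7 was lower at 0.886 ± 1.05 against 334 ± 236 CPM (log2 fold change -8.52, SE 1.26, edgeR adjusted p = 0.000543). LOC_Os03g45619 on chromosome 3 had 0 counts in Seedling, 0.558 CPM in Callus+AM replicate 1 and 436.5 CPM in replicate 2 (edgeR adjusted p = 0.0207). Its call ended without Callus+AM replicate 2 or either Seedling library (edgeR adjusted p 0.104 to 0.349). LOC_Os05g04500 on chromosome 5 was at 76.9 ± 83.3 CPM against 0 counts, at least 1855-fold higher (edgeR adjusted p = 0.0115), a call that ended without either Seedling library (edgeR adjusted p 0.07 and 0.0777). The bound for LOC_Os05g04500 was 433-fold without Callus+AM replicate 2, 3276-fold without Callus+AM replicate 1, 971-fold without Seedling replicate 1 and 884-fold without Seedling replicate 2. For LOC_Os03g16020 the log2 fold change was -7.29 without Seedling replicate 1 and -9.90 without Seedling replicate 2. For LOC_Os07g08150 it was -7.52 without Seedling replicate 2, -11.14 without Callus+AM replicate 1 and -7.67 without Callus+AM replicate 2. There were 4576 higher and 3712 lower genes, relative to a median log2 fold change of all genes of 0.161 with TMM and 0.132 with relative log expression factors. With limma on FPKM the split was 2666 higher and 3591 lower. The total of 8288 was 4693 without Seedling replicate 1, 4045 without Seedling replicate 2 (1644 higher, 2401 lower), 5367 without Callus+AM replicate 2 and 2429 with only these groups in the fit.

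The Ag plants differed from Seedling at 4166 higher and 4021 lower genes. LOC_Os06g51260 on chromosome 6 was lower at 0.278 ± 0.0892 CPM against 210 ± 70.5 CPM (SD, n = 2 each; log2 fold change -9.57, SE 1.03, edgeR adjusted p = 8.18e-05). LOC_Os08g06110 on chromosome 8 was lower at 2.60 ± 0.643 against 1329 ± 242 CPM (log2 fold change -8.99, SE 0.953, edgeR adjusted p = 7.14e-05). LOC_Os02g33550 on chromosome 2 had 0 counts in Seedling, 34.8 CPM in Ag replicate 1 and 0.348 CPM in replicate 2 (edgeR adjusted p = 0.0203). Its call ended without Ag replicate 1 or either Seedling library (edgeR adjusted p 0.0956 to 0.308). LOC_Os05g04500 was at 118.8 CPM in Ag replicate 1 and 0.616 CPM in replicate 2 (edgeR adjusted p = 0.0126), and its call ended without the same 3 libraries (edgeR adjusted p 0.0715 to 0.203). The total of 8187 was 5042 without Seedling replicate 1, 4393 without Seedling replicate 2 and 4907 without Ag replicate 1, and 5375 genes passed a test against 1.5-fold.

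In AgTi against Seedling, LOC_Os06g51260 was again lower at 0.218 ± 0.0815 CPM against 210 ± 70.5 CPM (SD, n = 2 each; log2 fold change -9.88, SE 1.04, edgeR adjusted p = 6.97e-05). LOC_Os03g16020 was lower at 0.407 ± 0.256 against 235 ± 238 CPM (log2 fold change -9.17, SE 1.62, edgeR adjusted p = 0.00142). LOC_Os01g16810 on chromosome 1 was at 9.61 ± 2.96 CPM against 0 counts in Seedling, at least 232-fold higher (edgeR adjusted p = 0.005). LOC_Os05g04500 was at 15.9 ± 18.2 CPM against 0 counts, at least 382-fold higher (edgeR adjusted p = 0.0254), a call that ended without either Seedling library or AgTi replicate 2 (edgeR adjusted p 0.109 to 0.123). The bound for LOC_Os05g04500 was 71.5-fold without AgTi replicate 2, 693-fold without AgTi replicate 1, 200.1-fold without Seedling replicate 1 and 182-fold without Seedling replicate 2. For LOC_Os01g16810 the bound was 121-fold without Seedling replicate 1 and 110.4-fold without Seedling replicate 2. LOC_Os03g16020 had a log2 fold change of -7.29 without Seedling replicate 1, -9.90 without Seedling replicate 2 and -9.99 without AgTi replicate 1. Altogether 3954 genes were higher and 4323 lower. The total of 8277 was 5341 without Seedling replicate 1, 4598 without Seedling replicate 2, 4054 without AgTi replicate 1 and 4975 without AgTi replicate 2.

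In AgBi against Seedling, LOC_Os05g12450 on chromosome 5 was lower at 5 ± 0.63 CPM against 97.2 ± 10.7 CPM (SD, n = 2 each; log2 fold change -4.28, SE 0.611, edgeR adjusted p = 0.00113). LOC_Os05g04500 was at 72.2 ± 44.5 CPM against 0 counts, at least 1742-fold higher (edgeR adjusted p = 0.0164). That call ended without either Seedling library (edgeR adjusted p 0.0907 and 0.0982). LOC_Os03g45619 was at 113.5 ± 105 CPM against 0 counts, at least 2737-fold higher (edgeR adjusted p = 0.0337), and this call ended without any 1 of the 4 libraries, Seedling replicate 1, Seedling replicate 2, AgBi replicate 1 or AgBi replicate 2 (edgeR adjusted p 0.0711 to 0.156). LOC_Os04g40410 on chromosome 4 was lower at 0.975 ± 0.804 against 22.4 ± 24.8 CPM (log2 fold change -4.53, SE 1.15, edgeR adjusted p = 0.0158), a call that ended without Seedling replicate 2 (log2 fold change -2.33, edgeR adjusted p = 0.18) or AgBi replicate 2 (log2 fold change -3.86, edgeR adjusted p = 0.123). Its log2 fold change was -5.35 without Seedling replicate 1 and -5.78 without AgBi replicate 1. The bound for LOC_Os05g04500 was 912-fold without Seedling replicate 1, 829.9-fold without Seedling replicate 2 and 983-fold without AgBi replicate 1. For LOC_Os03g45619 the bound was 1433-fold and 1304-fold without Seedling replicate 1 and 2, and 952-fold and 4522-fold without AgBi replicate 1 and 2. There were 3098 higher and 3000 lower genes. The total of 6098 was 2604 without Seedling replicate 1, 2302 without Seedling replicate 2 (917 higher, 1385 lower) and 2399 without AgBi replicate 2. With only these groups in the fit it was 3530, 2435 of them higher, and 3174 genes passed a test against 1.5-fold.

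In AMT+Ab against Seedling, LOC_Os05g09740 was at 56.2 ± 36 CPM against 0 counts, at least 1356-fold higher (SD, n = 2 each; edgeR adjusted p = 0.0203). LOC_Os05g04500 was at 50.5 ± 17 CPM, at least 1218-fold higher (edgeR adjusted p = 0.0153). Both calls ended without either Seedling library or AMT+Ab replicate 2 (edgeR adjusted p 0.0534 to 0.114). LOC_Os03g53340 was lower at 3.05 ± 1.08 against 101 ± 111 CPM (log2 fold change -5.05, SE 1.36, edgeR adjusted p = 0.0163), a call that ended without Seedling replicate 1 or either AMT+Ab library (edgeR adjusted p 0.0973 to 0.131). LOC_Os03g53340 had a log2 fold change of -2.87 without Seedling replicate 1 and -5.88 without Seedling replicate 2. LOC_Os03g16030 on chromosome 3 was lower at 6.25 ± 2.49 against 191 ± 216 CPM (log2 fold change -4.94, SE 1.49, edgeR adjusted p = 0.0269), and its call ended without the same libraries (edgeR adjusted p 0.129 to 0.208), with a log2 fold change of -2.61 without Seedling replicate 1 and -5.79 without Seedling replicate 2. The bound for LOC_Os05g09740 was 709.9-fold and 646-fold without Seedling replicate 1 and 2, and 741-fold without AMT+Ab replicate 2. For LOC_Os05g04500 the bound was 638-fold and 580.4-fold without Seedling replicate 1 and 2. There were 4133 higher and 3935 lower genes. The total of 8068 was 4456 without Seedling replicate 1, 3277 without Seedling replicate 2 (1344 higher, 1933 lower), 5070 without AMT+Ab replicate 1 and 2873 without AMT+Ab replicate 2, and 4726 genes passed a test against 1.5-fold.

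In AMT+Hb against Seedling, LOC_Os08g04500 on chromosome 8 was lower at 3.10 ± 0.538 CPM against 1785 ± 612 CPM (SD, n = 2 each; log2 fold change -9.17, SE 1.40, edgeR adjusted p = 0.000581). LOC_Os02g58310 on chromosome 2 was lower at 0.420 ± 0.00134 against 163 ± 36.6 CPM (log2 fold change -8.59, SE 0.787, edgeR adjusted p = 2.75e-05). LOC_Os05g04500 was at 63.4 ± 10.6 CPM against 0 counts, at least 1529-fold higher (edgeR adjusted p = 0.0114), a call that ended without either Seedling library (edgeR adjusted p 0.0657 and 0.075). LOC_Os03g45619 was at 78.0 ± 78.2 CPM against 0 counts, at least 1882-fold higher (edgeR adjusted p = 0.0279), a call that ended without either Seedling library or AMT+Hb replicate 1 (edgeR adjusted p 0.1 to 0.133). The bound for LOC_Os03g45619 was 985-fold and 897-fold without Seedling replicate 1 and 2, and 549-fold and 3215-fold without AMT+Hb replicate 1 and 2. For LOC_Os05g04500 the bound was 800.6-fold and 729-fold without Seedling replicate 1 and 2. There were 4772 higher and 4410 lower genes. The total of 9182 was 5537 without Seedling replicate 1, 4674 without Seedling replicate 2 and 4173 without AMT+Hb replicate 1.

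In PB against Seedling, LOC_Os04g39150 on chromosome 4 was at 81.6 ± 15.9 CPM against 0 counts, at least 1968-fold higher (SD, n = 2 each; edgeR adjusted p = 0.00496). LOC_Os05g09740 was at 90.7 ± 3.88 CPM, at least 2187-fold higher (edgeR adjusted p = 0.0134), a call that ended without either Seedling library (edgeR adjusted p 0.076 and 0.0795). LOC_Os08g32085 on chromosome 8 had 0 counts in PB and 5.44 ± 2.28 CPM in Seedling, at least 119-fold lower (edgeR adjusted p = 0.00828). LOC_Os01g08440 on chromosome 1 was lower at 15.3 ± 3.81 against 704.5 ± 147 CPM (log2 fold change -5.52, SE 0.618, edgeR adjusted p = 0.000154). For LOC_Os04g39150 the bound was 1030-fold and 938-fold without Seedling replicate 1 and 2, and for LOC_Os05g09740 it was 1145-fold and 1042-fold. For LOC_Os08g32085 the bound was 57.7-fold and 61.2-fold without PB replicate 1 and 2. There were 5208 higher and 4850 lower genes. The total of 10058 was 5372 without Seedling replicate 1, 5433 without Seedling replicate 2 (2200 higher, 3233 lower), 6124 without PB replicate 1 and 6606 without PB replicate 2.

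Callus+AM against Callus, which by their labels differ in AM, lies across the depth sets. LOC_Os05g38270 on chromosome 5 was lower at 4.68 ± 3.97 CPM against 63.8 ± 10.4 CPM (SD, n = 2 each; log2 fold change -3.78, SE 0.501, edgeR adjusted p = 0.0117). LOC_Os06g51260 was lower at 1.10 ± 1.34 against 19.1 ± 5.60 CPM (log2 fold change -4.15, SE 0.801, edgeR adjusted p = 0.0402). LOC_Os03g02190 on chromosome 3 was at 13.4 ± 5.74 CPM against 2 counts in both Callus libraries together, a ratio of 596-fold (95% interval 165 to 4924, edgeR adjusted p = 0.0464). LOC_Os05g38270 lost its call without Callus replicate 1 (edgeR adjusted p = 0.0593), LOC_Os06g51260 without either Callus library (edgeR adjusted p 0.0854 and 0.154), and LOC_Os03g02190 without either Callus library or Callus+AM replicate 2 (edgeR adjusted p 0.0523 to 0.244). LOC_Os07g04190 on chromosome 7 was higher at 11.01 ± 12.5 against 0.249 ± 0.0242 CPM (log2 fold change 5.45, SE 1.10, edgeR adjusted p = 0.0446), a call that ended without either Callus library or Callus+AM replicate 2 (edgeR adjusted p 0.0933 to 0.248). Without Callus+AM replicate 2 the log2 fold change was 3.15 for LOC_Os07g04190, -6.99 for LOC_Os06g51260 and -5.08 for LOC_Os05g38270. Without Callus+AM replicate 1 it was 6.29 for LOC_Os07g04190, -3.23 for LOC_Os06g51260 and -3.10 for LOC_Os05g38270. LOC_Os03g02190 was at least 212-fold higher without Callus replicate 1, and its ratio was 278-fold (95% interval 76.9 to 2293) without Callus replicate 2. DESeq2 called 2746 genes, 1770 of them higher. With edgeR over all groups, 5429 genes were at an unadjusted p below 0.05. After adjustment 209 passed, 107 higher and 102 lower, which does not show that few genes differed. The count was 2 without Callus replicate 1 (0 higher, 2 lower), 1565 without Callus+AM replicate 1 (1319 higher, 246 lower) and 537 without Callus+AM replicate 2. It was 387 with no filter, 25 against 1.5-fold and 0 with only these groups in the fit. With the replicate number as a block, an alternative fixed beforehand, it was 90 (38 higher, 52 lower). With Callus+AM replicate 2 and Ag replicate 2 exchanged, an alternative chosen after seeing the data, it was 1852 (753 higher, 1099 lower).

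Ag against Callus also lies across the depth sets. LOC_Os09g17740 on chromosome 9 was lower at 25.1 ± 8.51 CPM against 4384 ± 343 CPM (SD, n = 2 each; log2 fold change -7.45, SE 1.46, edgeR adjusted p = 0.0103). LOC_Os06g51260 was lower at 0.278 ± 0.0892 against 19.1 ± 5.60 CPM (log2 fold change -6.11, SE 0.923, edgeR adjusted p = 0.00442). Both calls ended without Ag replicate 1 (edgeR adjusted p 0.105 and 0.0573). LOC_Os03g02190 was at 23.3 CPM in Ag replicate 1, 0.858 CPM in replicate 2 and 2 counts in both Callus libraries together (edgeR adjusted p = 0.0125), and its call ended without Ag replicate 1 or either Callus library (edgeR adjusted p 0.0814 to 0.122). Its ratio of 537-fold (95% interval 149 to 4430) was 38.1-fold (10.6 to 315) without Ag replicate 1 and 1035-fold (287 to 8546) without Ag replicate 2. LOC_Os03g02190 was at least 191-fold higher without Callus replicate 1, and its ratio was 249.8-fold (69.2 to 2063) without Callus replicate 2. LOC_Os02g33550 was at 34.8 CPM in Ag replicate 1 and 0.348 CPM in replicate 2 against 3 counts in both Callus libraries together, a ratio of 521-fold (95% interval for counting error 178 to 2527, edgeR adjusted p = 0.0448). Its call ended without the same libraries (edgeR adjusted p 0.206 to 0.577), and its ratio was 10.3-fold (3.53 to 50.04) without Ag replicate 1. That ratio was 1032-fold (353 to 5004) without Ag replicate 2 and 835-fold (149.9 to 33000) without Callus replicate 1. There were 1716 higher and 1803 lower genes. The total of 3519 was 416 without Callus replicate 1 (107 higher, 309 lower), 964 without Callus replicate 2, 181 without Ag replicate 1, 1368 with only these groups in the fit, 1132 against 1.5-fold and 5716 with DESeq2. With the exchange of Callus+AM replicate 2 and Ag replicate 2 it was 4313 (2864 higher, 1449 lower).

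AgTi was compared with Ag. No gene passed with edgeR, where 1591 genes were at an unadjusted p below 0.05 and the smallest adjusted p was 0.668. DESeq2 called 68 genes, 25 higher and 43 lower, with 1994 at an unadjusted p below 0.05. In simulated counts for this comparison DESeq2 made 50 false calls, so the 68 may hold many. With limma on FPKM 0 genes were called, with 1174 at an unadjusted p below 0.05. With no filter on low counts edgeR called 1 gene, and with Callus+AM replicate 2 and Ag replicate 2 exchanged it called 784. LOC_Os06g51260 stood at 0.278 ± 0.0892 CPM in Ag and 0.218 ± 0.0815 CPM in AgTi (SD, n = 2 each). LOC_Os05g04500 stood at 59.7 ± 83.6 CPM in Ag and 15.9 ± 18.2 CPM in AgTi. LOC_Os01g16810 was at 2.32 and 5.07 CPM in the Ag libraries and at 9.61 ± 2.96 CPM in AgTi, and LOC_Os02g33550 was at 17.6 ± 24.4 CPM in Ag and at 0.427 and 3.71 CPM in the AgTi libraries. A simulation of this comparison recovered 3 of 50 genes changed 2-fold, 20 of 50 changed 4-fold and 32 of 50 changed 8-fold with edgeR. Most 4-fold changes and part of the 8-fold changes were missed, so 0 calls does not argue against changes of these sizes. The simulation gave all groups the same dispersion per gene. The real Ag libraries were more than 10-fold apart at 420 genes and the AgTi libraries at 70.

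AgBi was compared with Ag. LOC_Os01g65140 on chromosome 1 was lower at 0.384 ± 0.256 CPM against 31.5 ± 8.50 CPM (SD, n = 2 each; log2 fold change -6.36, SE 0.556, edgeR adjusted p = 8.94e-05). LOC_Os11g38160 on chromosome 11 was lower at 0.265 ± 0.0555 against 19.5 ± 10.2 CPM (log2 fold change -6.18, SE 1.08, edgeR adjusted p = 0.00263). LOC_Os02g15930 on chromosome 2 was at 5.95 CPM in AgBi replicate 1, 690 CPM in replicate 2 and 1.15 ± 0.109 CPM in Ag (edgeR adjusted p = 0.00523). Its call ended without AgBi replicate 2 or Ag replicate 1 (edgeR adjusted p 0.0577 and 0.0518), and its log2 fold change of 8.24 was 2.36 without AgBi replicate 2 and 9.22 without AgBi replicate 1. LOC_Os03g16030 was at 231 ± 321 CPM against 0.779 ± 0.343 CPM (log2 fold change 8.22, SE 1.76, edgeR adjusted p = 0.00694), a call that ended without AgBi replicate 2 or either Ag library (edgeR adjusted p 0.0509 to 0.117). LOC_Os03g16030 had a log2 fold change of 2.43 without AgBi replicate 2 and 9.21 without AgBi replicate 1. For LOC_Os01g65140 the log2 fold change was -7.26 without AgBi replicate 1, and for LOC_Os11g38160 it was -5.51 without Ag replicate 2. There were 3280 higher and 3404 lower genes. The total of 6684 was 2877 without Ag replicate 1, 3527 without AgBi replicate 2, 2395 with only these groups in the fit and 3566 against 1.5-fold.

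In AMT+Ab against AMT+Hb, LOC_Os04g57880 on chromosome 4 was lower at 2.77 ± 0.797 CPM against 656 ± 119 CPM (SD, n = 2 each; log2 fold change -7.89, SE 0.559, edgeR adjusted p = 2.9e-05). LOC_Os03g08580 on chromosome 3 was lower at 1.18 ± 0.358 against 238.7 ± 26.8 CPM (log2 fold change -7.67, SE 0.712, edgeR adjusted p = 0.000194). LOC_Os08g04500 was higher at 384 ± 168 against 3.10 ± 0.538 CPM (log2 fold change 6.95, SE 1.27, edgeR adjusted p = 0.00901), and LOC_Os06g12370 on chromosome 6 at 76.9 ± 1.81 against 0.824 ± 0.345 CPM (log2 fold change 6.54, SE 1.26, edgeR adjusted p = 0.011). The calls of LOC_Os08g04500 and LOC_Os06g12370 ended without AMT+Ab replicate 2 or either AMT+Hb library (edgeR adjusted p 0.0527 to 0.146). There were 833 higher and 859 lower genes. The total of 1692 was 496 without AMT+Ab replicate 1 (317 higher, 179 lower), 273 without AMT+Ab replicate 2, 611 without AMT+Hb replicate 1 (237 higher, 374 lower) and 239 without AMT+Hb replicate 2 (88 higher, 151 lower). It was 615 against 1.5-fold, 3017 with DESeq2 and 2745 with only these groups in the fit.

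PB was compared with the mean of the AMT groups, AMT+Ab and AMT+Hb. LOC_Os03g53340 on chromosome 3 was higher at 1119 ± 415 CPM (SD, n = 2) against 2.11 ± 1.26 CPM (SD, n = 4), with a log2 fold change of 9.21 (SE 1.18, edgeR adjusted p = 0.000475). LOC_Os04g01740 on chromosome 4 was higher at 837 ± 399 against 2.88 ± 2.27 CPM (log2 fold change 8.63, SE 1.52, edgeR adjusted p = 0.00191). LOC_Os08g32085 had 0 counts in PB and 36.1 ± 19.4 CPM in the AMT libraries, at least 790-fold lower (edgeR adjusted p = 0.00272). LOC_Os01g65140 was lower at 0.0916 ± 0.00381 against 19.3 ± 22.4 CPM (edgeR adjusted p = 0.000349), where AMT+Ab libraries were at 0.321 and 0.260 CPM and AMT+Hb libraries at 33.1 and 43.7 CPM. The only identifier with a matched name, LOC_Os01g19850 (CCC2, a cation-chloride cotransporter), was reported because of its name and not by the rule. It was higher in PB at 2.18 ± 0.867 CPM, against 0.852 ± 0.0422 CPM in AMT+Ab and 0.355 ± 0.00113 CPM in AMT+Hb (log2 fold change 1.98, SE 0.543, edgeR adjusted p = 0.0155). LOC_Os01g19850 did not pass in the other 14 comparisons (edgeR adjusted p 0.0624 to 0.991), with the lowest of these in PB against Seedling (log2 fold change 1.67, SE 0.658). The call of LOC_Os01g19850 in PB against AMT was kept in 9 of 9 other settings (log2 fold change 1.96 to 2.02) and ended without AMT+Ab replicate 2, AMT+Hb replicate 1 or PB replicate 2 (edgeR adjusted p 0.0511 to 0.143). For LOC_Os04g01740 the log2 fold change was 8.03 without PB replicate 1, and for LOC_Os08g32085 the bound was 383-fold and 407-fold without PB replicate 1 and 2. There were 4602 higher and 4176 lower genes. The total of 8778 was 5769 without AMT+Ab replicate 2, 4094 without PB replicate 1 (2602 higher, 1492 lower), 4367 without PB replicate 2 and 4522 against 1.5-fold.

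Some named genes with a call that ended without 1 library also lost it under other settings. With no filter on low counts, 22 of the 56 entries lost the call, all for LOC_Os05g04500, LOC_Os05g09740, LOC_Os03g45619, LOC_Os02g33550, LOC_Os03g14654 and LOC_Os04g40410, for LOC_Os03g53340 and LOC_Os03g16030 in AMT+Ab against Seedling, and for LOC_Os03g02190, LOC_Os06g51260 and LOC_Os07g04190 in Callus+AM against Callus. With limma on FPKM, 12 entries lost it, for LOC_Os03g14654 and LOC_Os07g04190, LOC_Os03g16030 in AMT+Ab against Seedling, LOC_Os03g45619 in 3 comparisons, LOC_Os05g04500 in Ag and AgTi, and LOC_Os02g33550 and LOC_Os03g02190 in 2 comparisons each. With only the groups compared, 12 entries lost it. These were the 4 of Callus+AM against Callus, both higher entries of AgBi against Ag, of Ag against Callus and of Ag against Seedling, LOC_Os03g14654 in Callus, and LOC_Os03g45619 in Callus+AM. Against 1.5-fold, 5 entries lost it, LOC_Os02g33550 in Ag against Callus, LOC_Os03g45619 in AgBi, and LOC_Os03g02190, LOC_Os06g51260 and LOC_Os07g04190 in Callus+AM against Callus. With the replicate number as a block, 4 entries lost it.

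**Figure D3:**
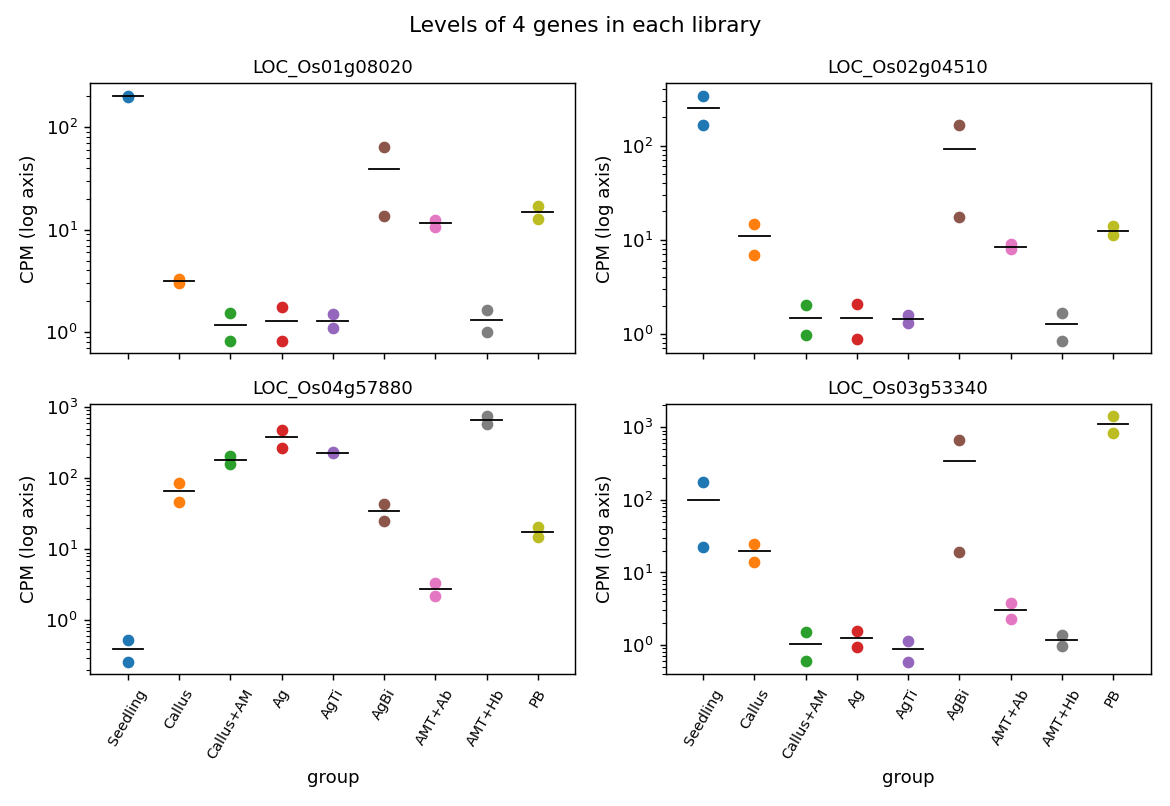
CPM on a log axis (y axis) of 4 named genes in the libraries of each group (x axis), with points for libraries and black lines for group means. LOC_Os01g08020 and LOC_Os02g04510 are highest on average in Seedling, LOC_Os04g57880 averages 656 CPM in AMT+Hb and 2.77 CPM in AMT+Ab, and LOC_Os03g53340 averages 1119 CPM in PB.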

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

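Without Seedling replicate 1 or 2, or a library of the other group, the counts of changed genes ranged as follows. They ran from 2015 to 2840 for Callus against Seedling, 4045 to 7468 for Callus+AM, 4393 to 6690 for Ag, 4054 to 5341 for AgTi, 2302 to 5870 for AgBi, 2873 to 5070 for AMT+Ab, 4173 to 6707 for AMT+Hb and 5372 to 6606 for PB. For the 8 groups together they ran from 4715 to 10726. Among the other comparisons they ran from 2 to 1565 for Callus+AM against Callus, 181 to 3468 for Ag against Callus, 2877 to 5094 for AgBi against Ag, 239 to 611 for AMT+Ab against AMT+Hb and 4094 to 7692 for PB against AMT, and stayed at 0 for AgTi against Ag. Relative log expression factors moved 0 of 16 counts by over 1.5 times, and limma on FPKM 0 of 15. Against a fold of 1.5, glmTreat left 3016 genes for Callus against Seedling, 5375 for Ag, 3174 for AgBi, 4726 for AMT+Ab and 5829 for the 8 groups together. It left 25 for Callus+AM against Callus, 1132 for Ag against Callus, 3566 for AgBi against Ag, 615 for AMT+Ab against AMT+Hb and 4522 for PB against AMT, as its stricter hypothesis implies. A fit of only the groups compared has fewer residual degrees of freedom. It gave 2429 for Callus+AM against Seedling, 3530 for AgBi against Seedling and 0 for Callus+AM against Callus. It gave 1368 for Ag against Callus and 2395 for AgBi against Ag. All of these are below the counts of the fit of all groups. For AMT+Ab against AMT+Hb it gave 2745, above the 1692 of the fit of all groups, a rise that fewer degrees of freedom alone do not account for. DESeq2 gave 2746 for Callus+AM against Callus, 5716 for Ag against Callus, 68 for AgTi against Ag and 3017 for AMT+Ab against AMT+Hb. With no filter on low counts, Callus+AM against Callus gave 387 and AgTi against Ag gave 1. The split of higher and lower calls was 921 and 1508 for Callus+AM against Seedling with only those groups, against 4576 and 3712. For Callus+AM against Callus, limma on FPKM gave 87 and 138, against 107 and 102. Except where the construction is named, the cause was not tested.

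Replicate numbers were checked as pairs across the 36 pairs of groups. The correlation of deviations from the group means across genes ran from -0.466 to 0.259 with a median of -0.031, above 0.1 in 9 pairs and below -0.1 in 14, so the numbers were not taken to pair the libraries. This does not exclude a pool shared by number. Replicate 2 libraries of 6 groups held traces of PB replicate 2 genes at 754.5 to 1466 ppm, as described below. With the replicate number as a block, Callus+AM against Callus gave 90 genes against 209, and 15 of 16 counts stayed within 1.5 times. These alternatives were chosen after seeing the data: a block in the 7 lower-depth groups, the exchange of Callus+AM replicate 2 with Ag replicate 2, thinning to the smallest library and leaving out isolated zeros. The block in the 7 groups gave 80 for Callus+AM against Callus. The exchange gave 1852 for Callus+AM against Callus (753 higher, 1099 lower), 784 for AgTi against Ag, and 4313 for Ag against Callus (2864 higher, 1449 lower). Thinning and the isolated zeros each moved 0 of 15 counts by over 1.5 times. The 56 entries of named genes kept their direction in 572 of 572 alternative values with all libraries. The entries had been picked for the largest fold changes, so a reversal was hardly possible and this tests little. Their calls were kept for 56 with DESeq2, 56 with relative log expression factors, 51 with glmTreat, 44 with limma, 44 with only the groups compared and 34 with no filter, and 30 entries lost the call without 1 library. Of the alternatives added later, thinning ended 1 call, that of LOC_Os03g02190 in Callus+AM against Callus, and the exchange 1, that of LOC_Os09g17740 in Ag against Callus. The block ended 4, that of LOC_Os02g33550 in Ag against Callus and those of LOC_Os03g02190, LOC_Os06g51260 and LOC_Os07g04190 in Callus+AM against Callus. The replicate number as a block over all groups, fixed beforehand, also ended 4 and kept 52 of the 56. The gene list tests, planned and with an estimated correlation, were not run, because the identifiers could not be matched to names.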

Other observations

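All tests and selections in this part were chosen after the result was seen. LOC_Os03g43100 on chromosome 3, LOC_Os06g15430 on chromosome 6 and LOC_Os11g13800 on chromosome 11 had 1 count each over both Seedling libraries and were at 1 CPM or more in the other 16 libraries. The ranges over the 16 libraries were 2.56 to 27.8 CPM for LOC_Os03g43100, 1.09 to 2.90 CPM for LOC_Os06g15430 and 21.0 to 41.3 CPM for LOC_Os11g13800. In PB, 17 genes were at 1 CPM or more in both libraries and at 2 counts or fewer in each of the other 16. LOC_Os01g10490 on chromosome 1 was the highest of these, at 13.4 ± 5.33 CPM (SD, n = 2). LOC_Os03g47896 on chromosome 3 had 3.13 ± 0.975 CPM in PB and LOC_Os07g37090 on chromosome 7 had 1.16 ± 0.217 CPM, with 0 counts in all other libraries. Some of the 17 were uneven between the PB libraries, such as LOC_Os04g49150 at 6.93 ± 5.07 CPM. Whatever their level in other groups, 151 genes were at 5 CPM or more in PB replicate 2 and at 2 counts or fewer in PB replicate 1. The reverse held for 0 genes.

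Neighbouring genes changed in the same direction more often than after permutation of genes within chromosomes, from 1.24 times in PB against Seedling and PB against AMT to 2.3 times in AMT+Ab against AMT+Hb. Outside this range was Callus+AM against Callus, with 4 pairs against 0.841 (permutation p = 0.01), and AgTi against Ag had 0 calls. In Callus against Seedling, 942 neighbouring pairs were called in the same direction against a permuted mean of 510.1 (permutation p = 0.001, the smallest that 1000 permutations can give). In PB against Seedling there were 2393 against 1930, and in AMT+Ab against AMT+Hb 126 against 54.8 (permutation p = 0.001 each). Neighbours were consecutive identifiers among the tested genes, without coordinates. The permutation moves calls between genes, so its p-value does not measure variation between the 2 libraries of a group. Overlapping genes or near-identical copies that share reads could also give such pairs, which was not tested. Genes changed in 2 comparisons that share no library were also counted. Callus against Seedling and PB against AMT shared 776 in the same direction and 953 in opposite directions. Independent lists would share 848.7 and 852, so this overlap was near that of independent lists. AgBi against Ag and Callus against Seedling shared 523 genes in the same direction and 1317 in opposite directions, where independent lists would share 648 and 647. AgBi against Ag and AMT+Ab against AMT+Hb shared 810 in the same direction and 58 in opposite directions, where independent lists would share 214.5 and 214.3. Over the 378 pairs of group differences with no group in common, the median absolute correlation across genes was 0.207. AgBi against Ag correlated with AMT+Ab against AMT+Hb at 0.277, which 36% of these pairs reached, and with Callus against Seedling at -0.116, which 73% reached in absolute size.

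AgBi against Ag and PB against AMT, which share no library, shared 3634 genes in the same direction and 87 in opposite directions, where independent lists would share 1111 and 1113. A correlation common to any pair of group differences cannot be told apart. The correlation across genes was 0.512, which 16 of the 378 pairs (4.23%) reached in absolute size, between the shares of 5% and 1% set as bounds. The 378 pairs are built from the same group means and include AgBi against Ag with PB against AMT+Ab or AMT+Hb alone. None of them uses the mean of the AMT groups. The share is therefore not a frequency among unrelated differences, and no conclusion is drawn from it. The mean correlation across genes was 0.45 with crossed replicate numbers and 0.406 with the same numbers, which does not test a pool shared by a number, because each group holds both numbers and such a shift cancels in both comparisons. Thinning left 97.7% of shared genes in the same direction, but the totals of these libraries differed by at most 1.25 times, so it hardly tests depth. Treatments and the state of the plants when sampled, which may act on many genes at once, stay open and were not tested.

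Callus+AM replicate 1 and Ag replicate 2 lay closer to AgTi libraries than to their own groups. Exchanged labels of Callus+AM replicate 2 and Ag replicate 2 cannot be told apart, because Callus+AM replicate 1 and Ag replicate 2 differed by a median of 0.31 on the log2 scale and Ag replicate 1 and Callus+AM replicate 2 by 0.61, where labelled pairs differed by 0.56 in Callus+AM, 0.52 in Ag and 0.26 to 0.54 in the other 7 groups. Both stayed nearest to AgTi after thinning (2 of 2) and without the 200 most abundant genes (2 of 2). These hardly test depth or a few abundant genes, because the totals differed by at most 1.15 times and ranks over 26374 genes depend little on 200. A single wrong label stays open too, and no biological explanation was tested.

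In PB replicate 2, 31 genes held 158888 counts, and the replicate 2 libraries of 6 other groups held traces of them at 754.5 to 1466 ppm of the PB replicate 2 level. In 10 other libraries the traces were 25.89 to 204.6 ppm, and in PB replicate 1 they were at 5509 ppm. PB replicate 2 molecules read under the sample tags of 5 of these libraries may account for the traces there, with a median chi-square per degree of freedom of 1.46 (0.669 to 2.25) against the PB replicate 2 profile. As the only source of the counts in Callus+AM replicate 2 they were argued against, at 45.9. Low expression by the plants themselves cannot be told apart, because the lowest level in the 5 libraries was 3.69 times the highest in the replicate 1 libraries of the 6 groups and plants could differ by any ratio.

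In Callus replicate 1, 30 genes were listed at 0 counts and 0 FPKM while the other 17 libraries had at least 1 CPM, 10 of them on chromosome 2, and Callus replicate 2 held 121 to 3351 counts of each.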
